A study of Mus musculus with 2 samples.

How the data were processed

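Islets of WT and KO mice were isolated by collagenase perfusion of the pancreas, picked by hand and kept in RPMI-1640 medium with fetal bovine serum, and libraries were made from total RNA with a SMARTER mRNA kit, per the labels' protocols. There were 2 samples, 1 library per genotype, grouped by the genotype label. The authors deposited 1 table of FPKM values, reads or fragments per kilobase of gene per 1000000, with 1 column per library. The genome build was mm10 (GRCm38), per the submitters' processing notes; the aligner, the counting tool, the annotation, strand settings and filters are not given in the sources used here. The labels describe the knockout as one of β-cells; the deleted exon and the driver of recombination are not given in the sources used here.

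The deposited FPKM values were used without further scaling. The values were searched for whole read numbers, each divided by a whole gene length and by 1 library total per column. Simple ratios of reads between the columns and a scan over candidate totals gave totals of 14537660 for the library labelled KO and 19097001 for WT, a ratio of 1.31. With these totals, lengths from 60 to 30000 nucleotides were searched for each gene. In that search 17178 of 17245 genes (99.6%) came out whole within 1e-05 of a read plus 1e-09 times the read number. Among genes above 1 FPKM in both libraries 99.9% came out whole, against 2.70% of 999 shuffled pairs. The smallest whole reads that give a gene's values in both libraries were used for exact Clopper-Pearson 95% intervals of the ratio of FPKM values. The true reads are these or a whole multiple of them, so an interval can be too wide. The smallest reads summed to 91.3% and 90.1% of the totals. On 3807 simulated genes the true reads were such a multiple for 99.97% and equal for 83.7%. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals cover counting error only. A count test was not run, because the unit is FPKM and there is no replicate.

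Differences are log2((KO + 1)/(WT + 1)) with a pseudocount of 1 FPKM, which understates the change of low genes. Genes with at least 1 FPKM in either library were kept, and a gene was called higher or lower at a 2-fold difference on that scale. For each list of genes the median over its kept members was set among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. A list was called apart above percentile 97.5 or below percentile 2.5, and lists with under 5 kept members were not called. No p-value was computed. The procedure was tested on simulated data, a simulated library against the WT library over 16961 genes. Of 50 lists of 25 genes shifted by 0.6, 92% were called in each direction, and 96% of 100 unchanged lists were not called. The simulated lists held random genes with independent noise. These shares therefore do not give the rate of false calls for groups whose genes vary together. Of 200 genes changed 4-fold, 92% were called in each direction. Calls among unchanged single genes were not counted.

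The 35 lists, the limits, the rule for named genes and the alternatives, except where said, were set before the data were examined. The lists covered the cGAS-STING pathway, C/EBP factors, interferon-stimulated genes, cell-cycle phases and inhibitors, mitogenic and lactogen signalling, islet cell types and β-cell maturity, other pancreatic cell types, stress and inflammation, metabolism, DNA repair, apoptosis, and housekeeping complexes. The rule named Cgas, Sting1 and Cebpb, up to 4 members of each list with the widest log2 ratios, of which 2 to 4 are given, and the 15 highest and 15 lowest genes with at least 5 FPKM in either library, leaving out predicted genes and pseudogenes. Other genes were chosen after their values were seen: Ins1, Ins2, Gcg, Mki67, Gipr, Nnat, Ikbke, Ifi204, Igfbp4, Reg3a, Il1r1, Atf3 and Pmvk. Of the named genes, Ddit3, Cebpz, Rbl2, Ptprn2, Eng, Tagln, Atf6, Cryab, Xrcc6, Cela2a and Zfp692 overlap another annotated gene, so their reads are less certain. Values of a few single genes that the rule takes are not reported here.

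Alternatives were pseudocounts of 0.1 and 5, no floor and a floor of 5 FPKM, and 3 scalings (a sum of 1000000 per library, the median ratio, and equal sums without the 20 highest genes). For lists they also were random lists not matched on expression, the mean in place of the median, and leaving out members shared between lists. An alternative chosen after seeing the data removed a lowess trend (fraction 0.3, 3 iterations) of the log2 ratio on GC content and then on log2 length of the transcript, for 12374 of 12428 expressed genes (99.6%). GC content and length came from the longest protein-coding GENCODE M21 transcript of a gene, or else its longest transcript. Coordinates came from RefSeq on GRCm38.p6, which matched 17155 symbols, 17031 of them protein-coding. The 6 gene groups of the other observations were also chosen after seeing the data. They were ER translocation, vesicle coats, heat-shock proteins, mitochondrial ribosomal proteins, Zfp zinc-finger proteins and aminoacyl-tRNA synthetases. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.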

Results

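RNA was sequenced from pancreatic islets of mice, the clusters of hormone-secreting cells in which insulin-producing β-cells are the most common type. The labels name 2 genotypes, wild type (WT) and a β-cell knockout of the cytosolic DNA sensor cGAS (KO), with 1 library per genotype, so no difference given here has a replicate check. The deposited FPKM values (fragments or reads per kilobase of gene per 1000000) covered 17245 gene symbols. A search over library totals, described with the processing, gave 14537660 reads for KO and 19097001 for WT, with which the values of 17178 genes came out as whole read numbers within 1e-05 of a read plus 1e-09 times the read number. A gene with at least 1 FPKM in either library was counted as expressed, which held for 12428 genes. Because Cgas RNA was not lower in the KO library, it is called the library labelled KO throughout, and every direction given here is between the 2 libraries as labelled.

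The first comparison asked whether the targeted gene and the other genes named in the study's title differed between the libraries. Cgas, which makes the second messenger cGAMP when it binds cytosolic DNA, was at 0.521 FPKM in the library labelled KO and 0.205 FPKM in the WT library, a ratio of 2.55 (exact 95% interval 1.35 to 4.98). These values rest on few reads, at least 31 and 16. Sting1, the receptor for cGAMP, was at 2.96 and 1.37 FPKM, a ratio of 2.15 (1.55 to 3.01). Cebpb, a leucine-zipper transcription factor, was at 10.4 and 7.62 FPKM, a ratio of 1.37 (1.13 to 1.65). On the log2(FPKM + 1) scale the differences were 0.34 for Cgas, 0.74 for Sting1 and 0.41 for Cebpb, all short of the 2-fold limit, and this scale understates the change of low genes such as Cgas. With a pseudocount of 0.1 the Cgas difference was 1.03, and after removal of a trend with GC content and transcript length that of Cebpb was -0.35. In the mouse genome build GRCm38.p6, Cgas lies on chromosome 9 from 78430518 to 78443237, Sting1 on chromosome 18 from 35733678 to 35740554 and Cebpb on chromosome 2 from 167688915 to 167690432. A gene total does not show whether reads came from a deleted exon or from cells outside the β-cell lineage. The intervals cover counting error only.

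The genes with the widest differences were taken among those with at least 5 FPKM in either library, leaving out predicted genes and pseudogenes. Those furthest below the WT library were genes of the exocrine pancreas. Those furthest above it were mixed, with 4 immediate-early or heat-shock response genes among the 15 highest. Ctrb1, a chymotrypsinogen, was at 29.8 against 753 FPKM, 25.3-fold lower in the library labelled KO (22.8 to 28.0). All of the 15 lowest genes were digestive enzymes, other acinar secretory products or members of the Reg family, among them Pnlip, Cpa1, Cela2a, Prss2, Sycn, Klk1 and Reg1. The 15 highest included Fos, an immediate-early transcription factor, at 42.7 against 5.59 FPKM (7.64-fold, 5.97 to 9.89). They also included Hspa1a and Hspa1b, near-identical heat-shock genes whose reads cannot be assigned with certainty, at log2 ratios of 2.31 and 2.25, and Ccn1, a matricellular protein, at 2.18. The others were Sap25, Echdc2, Lgals4, Igflr1, Npff, Crybb3, Myl7, Fam193b, Doc2g, Zfp692 and Lmtk3, with log2 ratios between 2.09 and 2.61. Among all expressed genes, 868 were at least 2-fold higher and 482 at least 2-fold lower in the library labelled KO, and 11078 lay within 2-fold. Higher genes made up 64.3% of these calls, against 46.5% when each library was scaled to a sum of 1000000 and 44.8% when scaled to equal sums without the 20 highest genes. The median gene lay at 0.077, with quartiles of -0.35 and 0.51.

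Gene groups fixed before the data were examined were compared through the median log2 ratio of their expressed members and its percentile among 10000 random lists of the same size and expression level, which describes these libraries only. Of 32 groups with at least 5 expressed members, 12 were higher and 6 lower than the central 95% of random lists. For lists of independent random genes 1.6 would fall outside. Genes of a group can vary together, and the random lists were not matched on GC content or length. The number 1.6 is therefore not a chance level for these groups.

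The study's title concerns β-cell proliferation, so cell-cycle genes were compared next. Of 35 expressed genes of G1/S and DNA replication, 2 were at least 2-fold higher, Rfc2 (37.8 against 17.9 FPKM, 2.11-fold, 1.89 to 2.36) and Orc6 (17.0 against 7.88 FPKM, 2.16-fold, 1.84 to 2.54), subunits of the clamp loader and of the origin recognition complex. Ccnd2, a D-type cyclin of islet cells, was at 69.6 against 135 FPKM, a log2 ratio of -0.95. The group median was 0.047, at percentile 22.3 of random lists. Of 64 fixed genes of G2/M and mitosis only 21 reached 1 FPKM in either library, with a median of 0.35 at percentile 79.2. Mki67, the marker behind Ki-67 staining, was at 0.839 and 0.660 FPKM, with an interval of the ratio from 0.985 to 1.64, so no difference was detectable at this depth. The kinetochore gene Spc25 was the single mitotic gene past the 2-fold limit, lower at 63.9 against 184 FPKM, and is a neighbour of the abundant β-cell gene G6pc2 on chromosome 2. Stmn1 and Mybl2 had log2 ratios of 0.85 and 0.76.

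Among cell-cycle inhibitors and p53 targets, Cdkn1a, the CDK inhibitor p21, was higher (29.3 against 13.3 FPKM, 2.20-fold, 1.89 to 2.58) and Rbl2, a pocket protein of the retinoblastoma family, was lower (log2 ratio -1.20). The other 22 of 24 expressed members lay within 2-fold, and the median was -0.051 at percentile 26.5, while the mean was above 0. Genes of β-cell mitogenic signalling had a median of -0.17 at percentile 3.51, with none of 32 past 2-fold. Its widest member, the matricellular gene Ccn2, was at 0.96, and the prolactin receptor Prlr and the insulin receptor substrate Irs2 were at -0.84 and -0.82; with the GC and length trend removed Prlr was at -0.23. This group fell below percentile 2.5 in 5 of the 11 alternative settings. Lactogen-responsive genes had a median of -0.067 at percentile 21.7 over 6 genes, with Bcl6 at 0.69 and Ehhadh at -0.63. Genes of DNA damage repair had a median of -0.17 at percentile 7.59, with none of 19 past 2-fold, Xrcc6 at 0.91 and Atm at -0.73. The apoptosis group had a median of 0.19 at percentile 79.3; 3 of its 22 genes were at least 2-fold higher, the death receptor Fas (1.35), the BH3-only gene Bbc3 (1.23) and Casp12 (1.05).

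Genes of the cGAS-STING pathway and interferon-stimulated genes were higher as groups in the library labelled KO. Of 16 expressed genes of the cGAS-STING pathway, 5 were at least 2-fold higher: Ikbke, Ifi204, the cytosolic exonuclease Trex1 (20.0 against 6.49 FPKM, 3.07-fold, 2.17 to 4.42) and the transcription factors Irf3 (2.81-fold, 2.53 to 3.12) and Irf7 (3.05-fold, 2.53 to 3.70). The ubiquitin ligase Trim56 was lower (1.98 against 8.13 FPKM, 4.12-fold, 2.60 to 6.82). The pathway median was 0.57 at percentile 99.6; without a floor on low values it was 0.35 at percentile 96.4, and with a floor of 5 FPKM 0.35 at percentile 91.7. Of 49 interferon-stimulated genes, 16 were at least 2-fold higher and none lower, with a median of 0.74 above all random lists. Isg15, a ubiquitin-like modifier, was at 8.10 against 1.52 FPKM (5.31-fold, 3.30 to 8.90), Oas2, a sensor of double-stranded RNA, at 5.58 against 1.12 FPKM, and Ifi44 had a log2 ratio of 1.32. The 6 expressed C/EBP factors had a median of 0.44 at percentile 92.0, with none past 2-fold, Ddit3 at 0.83, Cebpa at 0.66 and Cebpz at -0.57; with the GC and length trend removed these were 0.20, 0.17 and -0.17. Ddit3 overlaps Mbd6 and Mars1, and how reads in the overlap were counted is not given. Macrophage markers were higher in the same library, with a median of 0.78.

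Genes that mark mature β-cells were lower as a group in the library labelled KO. Of 39 expressed identity genes, 9 were at least 2-fold lower and 4 at least 2-fold higher. The lower ones included the incretin receptor Glp1r (17.9 against 99.2 FPKM, 5.53-fold, 4.97 to 6.17), the fatty-acid receptor Ffar1 (10.4 against 52.6 FPKM, 5.08-fold, 4.24 to 6.13) and the glucose-6-phosphatase G6pc2 (427 against 1334 FPKM, 3.13-fold, 3.04 to 3.21). Ptprn2, a protein of the secretory granule membrane, had a log2 ratio of -1.73. The higher genes included the other incretin receptor Gipr at 1.53, Nnat at 1.09 and Ins1. The group median was -0.40, below all random lists, and -0.24 at percentile 4.81 after removal of the trend with GC content and length. Genes of the insulin granule and of exocytosis had a median of -0.27 at percentile 0.59, with 2 of 30 at least 2-fold lower, the granin Scg2 (868 against 2684 FPKM, 3.09-fold, 3.06 to 3.13) and Exph5 (-1.12). Genes normally kept low in mature β-cells, or active in immature ones, had a median of 0.64 at percentile 99.9, with 5 of 20 at least 2-fold higher, namely the neuropeptide Npy (147 against 50.1 FPKM), Ly6a, Zfp36l1, Cxcl12 and Igfbp4. Ly6a and Cxcl12 are also expressed by endothelial and stromal cells, whose markers were higher in the same library. Values of whole islets do not show which cells the RNA of the other members came from, so the group median is not specific to β-cells.

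The insulin genes, chosen after their values were seen, differed in opposite directions. Ins1 was at 237131 against 113793 FPKM and Ins2 at 182558 against 250577 FPKM, so Ins1 made up 56.5% of their sum in the library labelled KO and 31.2% in the WT library. Both genes together held 55.6% and 53.4% of the FPKM summed over all listed genes. Their transcripts are close copies, so how reads were divided between them is uncertain. Glucagon, Gcg, also chosen after its values were seen, was at a log2 ratio of -0.026. Alpha-cell markers had a median of -0.063 at percentile 27.1, with 1 of 13 past the limit, Sphkap at -1.19, and Irx2 at 0.68. Markers of delta, PP and epsilon cells had a median of 0.58 at percentile 95.9; peptide YY, Pyy, was the 1 of 10 at least 2-fold higher (4781 against 2139 FPKM), and somatostatin, Sst, had a log2 ratio of 0.64. With the GC and length trend removed, Pyy was at 0.31, no longer past 2-fold, and Sst at -0.079.

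The exocrine difference covered nearly the whole acinar group. Of 31 expressed acinar markers, 28 were at least 2-fold lower in the library labelled KO, with a median of -3.34 below all random lists. Pancreatic lipase, Pnlip, was at 8.95 against 164 FPKM (18.3-fold, 15.9 to 21.2), carboxypeptidase Cpa1 at 6.48 against 121 FPKM (18.6-fold, 15.8 to 22.1) and the granule lectin Zg16 at 4.64 against 104 FPKM. Trypsin, elastase and amylase genes belong to families of close copies, so their single values are less certain than the group. All 5 expressed Reg genes, which encode secreted lectins, were lower, with a median of -2.71, Reg1 at -3.83, Reg2 at -3.68 and Reg3b at -2.71; the others were Reg3a and Reg3d. Ductal markers did not stand apart, with a median of 0.35 at percentile 86.8 and 2 of 17 at least 2-fold higher, Anxa3 (1.24) and Ambp (1.16).

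Markers of vascular, stromal and myeloid cells were higher in the library labelled KO. The endothelial group had a median of 0.99 with 12 of 24 at least 2-fold higher, including von Willebrand factor, Vwf (10.7 against 2.77 FPKM, 3.85-fold, 3.46 to 4.28), Egfl7 (3.19-fold, 2.90 to 3.51) and the co-receptor Eng, at a log2 ratio of 1.39. The fibroblast, stellate-cell and pericyte group had a median of 0.80 with 6 of 28 at least 2-fold higher, including the contractile genes Tagln (1.53) and Acta2 (1.34). The macrophage and dendritic-cell group had a median of 0.78 with 9 of 25 at least 2-fold higher, including Aif1 (1.74), the complement genes C1qb (1.51) and C1qa (1.29), and lysozyme, Lyz2 (1.16). All 3 medians lay above all random lists and no member was at least 2-fold lower. Glial markers had a median of 0.36 at percentile 87.5 over 11 genes, with Cryab at 0.97 and Fabp7 at 0.62. The 6 adipocyte and erythrocyte markers had a median of 0.75 at percentile 98.6, with the fatty-acid carrier Fabp4 at 1.23 and the α-globin Hba-a2 at 1.14, and 0.18 at percentile 77.4 after the GC and length trend was removed. Only 4 lymphocyte markers were expressed, too few for a percentile, with Cd52 at 1.19 and Cd79a at -1.14. The 4 expressed sex-linked genes, also too few for a percentile, were Y-linked and present in both libraries, with Ddx3y at 9.94 and 13.4 FPKM and Eif2s3y at 10.7 and 6.27 FPKM. Xist and Tsix, also in that fixed group, had no values, so the group does not show whether female RNA was present too.

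Immediate-early and inflammatory genes were higher, and genes of the endoplasmic reticulum (ER) stress response and of cholesterol synthesis were lower, as groups in the library labelled KO. Of 27 immediate-early and dissociation-response genes, 13 were at least 2-fold higher, led by Fos, Hspa1a, Hspa1b and Ccn1, with a median of 0.99 above all random lists. The NF-kB and inflammatory group had a median of 0.85, above all random lists, with 7 of 24 at least 2-fold higher, including the adhesion molecules Vcam1 (6.98 against 1.83 FPKM, 3.81-fold, 3.08 to 4.73) and Icam1 (1.30) and the chemokine Cxcl2 (1.24), and with Il1r1 lower. Acute-phase genes had a median of 0.73 at percentile 99.5, with complement factor B, Cfb, at 1.57 and C3 at 1.06; with a floor of 5 FPKM the median was 0.91 at percentile 97.1 over 5 genes, within the random range. The ER stress group had a median of -0.61 below all random lists, with 7 of 36 at least 2-fold lower, including the chaperones Dnajb9 (60.5 against 232 FPKM, 3.84-fold, 3.64 to 4.05) and Hyou1 (2.77-fold, 2.69 to 2.85) and the stress sensors Atf6 (-1.58) and Ern1 (-1.38). The 1 member at least 2-fold higher was Atf3, which is also an immediate-early gene. Cholesterol synthesis genes had a median of -0.55 below all random lists, with 4 of 23 at least 2-fold lower, including squalene epoxidase, Sqle (2.54-fold, 2.27 to 2.85), and the sterol-regulated ER protein Insig1 (-1.12), and with Pmvk higher. Hypoxia and glycolysis genes had a median of -0.10 at percentile 16.4, with 3 of 25 at least 2-fold lower, Ero1a (-1.16), Pgam1 (-1.12) and Hif1a (7.12 against 15.3 FPKM).

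Cytosolic ribosomal protein genes were higher as a group in the library labelled KO. All 80 expressed cytosolic ribosomal protein genes lay above 0, 23 of them at least 2-fold higher, with a median of 0.86 above all random lists, Rpl13a at 895 against 335 FPKM and Rps19 at 1.40. Ribosomal protein genes have many pseudogene copies, so their single values are uncertain. Nuclear-encoded oxidative phosphorylation genes had a median of 0.49 at percentile 99.9, with 15 of 79 at least 2-fold higher, Atp5e at 1.55 and Uqcc2 at 1.49; after removal of the GC and length trend the median was 0.095 at percentile 97.0. Proteasome subunits had a median of 0.19 at percentile 75.4, with the interferon-induced subunits Psmb10 (1.12) and Psmb8 (1.04) the 2 of 37 at least 2-fold higher. No gene symbol in the deposited values began with mt-, so the fixed group of mitochondrially encoded genes had no members to analyse.

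Log2 ratios differed with transcript GC content and length across the whole transcriptome. Over 12374 genes with both values, Spearman's rho across genes, which are not independent replicates, was 0.42 with GC content and -0.39 with length. Split into 5 bins of GC content, genes in the lowest bin (up to 44.5%) had a median of -0.28 and those in the highest (from 56.2%) 0.45. Of 5 length bins, the shortest (up to 1745 nucleotides) had a median of 0.47 and the longest (from 5079) -0.26. After a smooth trend on both was removed, an alternative chosen after seeing the data, 557 genes were at least 2-fold higher and 272 at least 2-fold lower. Of 104 genes taken by the naming rule, past 2-fold and with a trend value, 27 came within 2-fold and none changed sign. Those named here were Trex1, Rbl2, Cdkn1a, Exph5, Npy, Sphkap, Pyy, Ambp, C1qb, C1qa, Cd52, Hba-a2, Ero1a, Hif1a, Insig1, Bbc3, Rpl13a, Atp5e, Uqcc2, Psmb10 and Psmb8. Of the genes chosen after their values were seen, Atf3, Igfbp4, Il1r1, Ins1, Nnat and Pmvk also came within 2-fold. Of the 18 groups that stood apart, 15 still did, the exceptions being β-cell identity, oxidative phosphorylation, and adipocyte and erythrocyte markers.

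**Figure D1:**
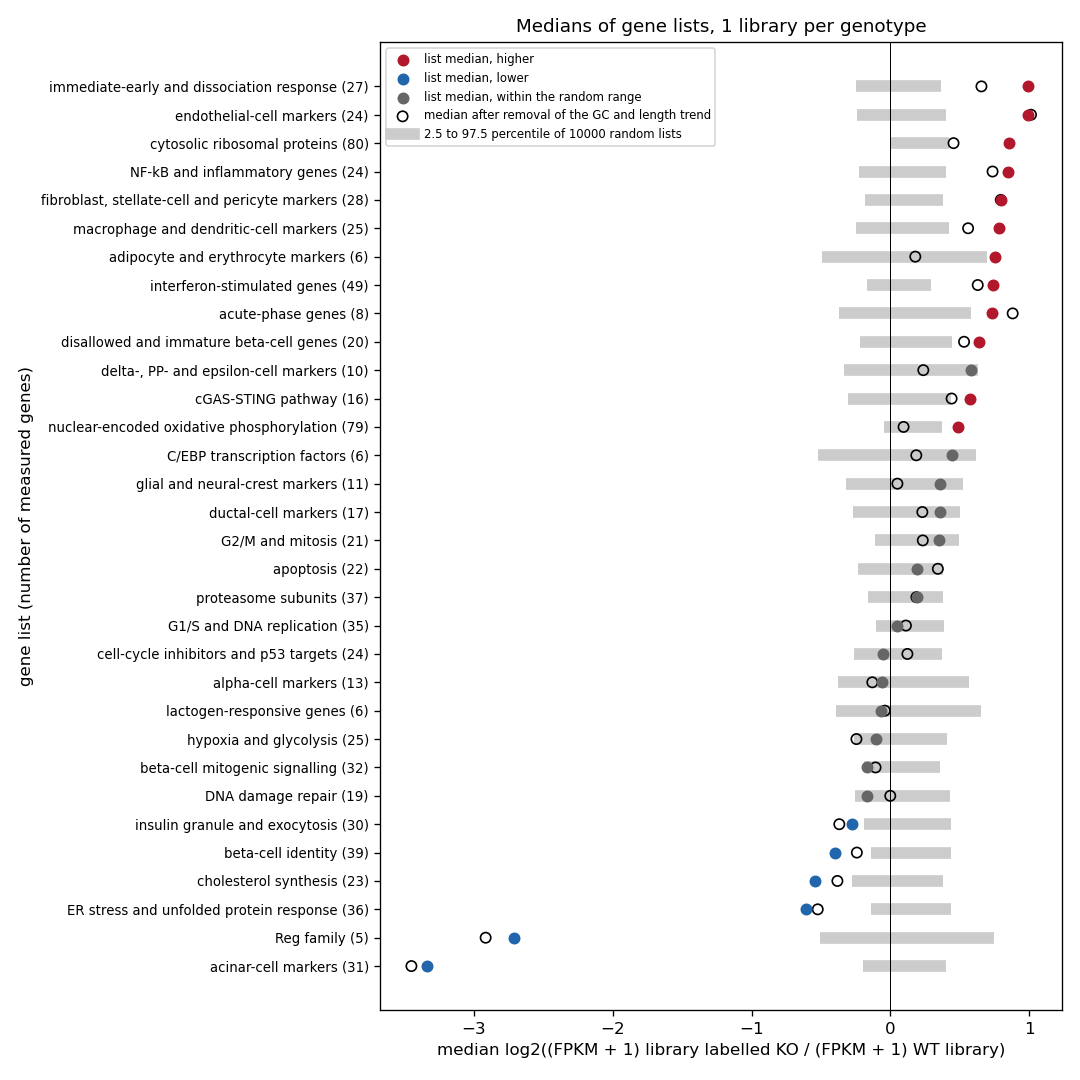
Median log2 ratio, library labelled KO over WT, on log2(FPKM + 1), for each of 32 gene groups (filled points, coloured by whether the median lies outside the random range), with the central 95% of 10000 random lists of the same size and expression as grey bars and the median after removal of the GC and length trend as open circles. Acinar markers (-3.34) and Reg genes (-2.71) lie far below their random ranges, and endothelial markers and immediate-early genes (both 0.99) lie furthest above.

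**Figure D2:**
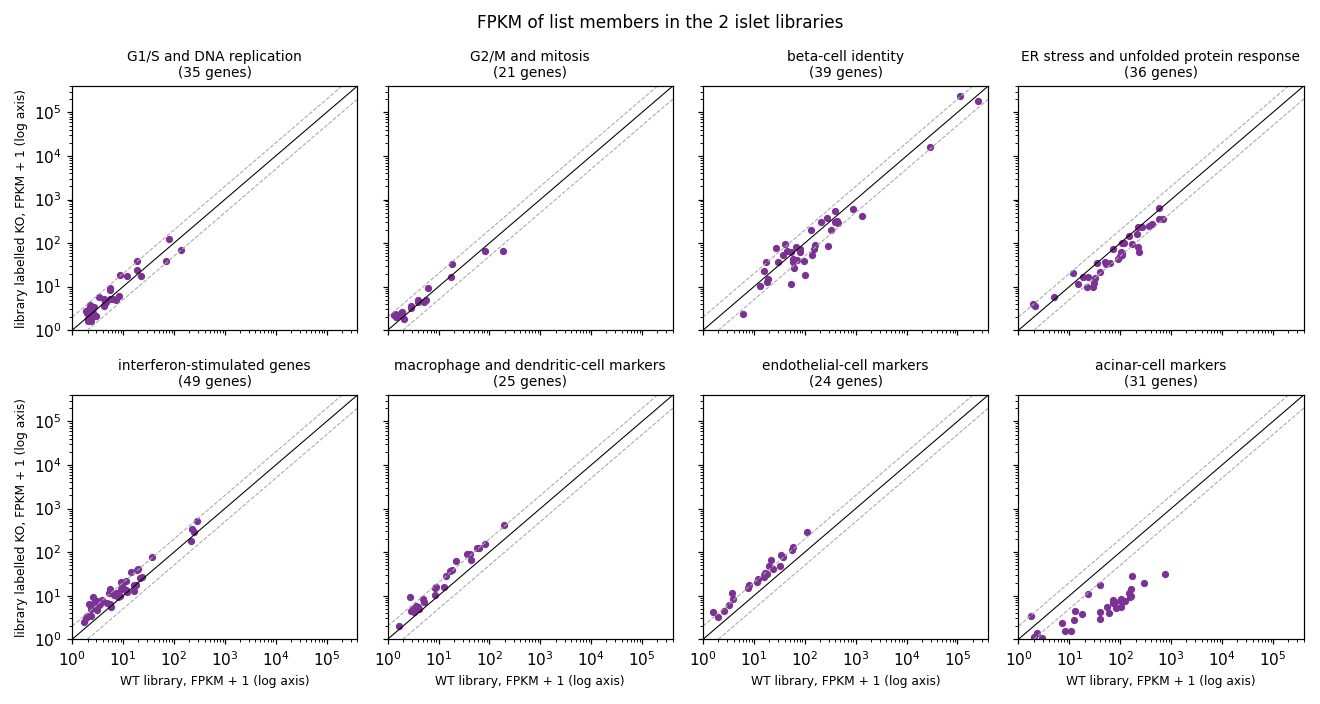
FPKM + 1 of each expressed member of 8 gene groups in the WT library and in the library labelled KO, 1 point per gene, on logarithmic axes, with a solid line at equality and dashed lines at a 2-fold difference. In the acinar panel 28 of 31 genes lie beyond the dashed line on the WT side, and in the endothelial panel 12 of 24 lie beyond the line on the side of the library labelled KO.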

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

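No setting turned the direction of a called group, or of a called gene among the 157 named genes that were recomputed. Of the 18 groups that stood apart, 13 did so under each of 11 alternatives that gave a value, and 9 of the 14 others stayed within the random range; 3 groups had too few genes with a floor of 5 FPKM and 1 without shared members. For the named genes, 876 of 941 recomputed log2 ratios stayed within 1.5-fold and 65 moved further. With a pseudocount of 0.1 the Cgas difference was 1.03 and 1556 genes were higher; with a pseudocount of 5, 305 were higher and 181 lower, since the pseudocount shrinks low genes. Scaling to a sum of 1000000 gave 793 lower genes and a median gene of -0.049 in place of 0.077; equal sums without the 20 highest genes gave 567 higher. Removal of the GC and length trend, chosen after seeing the data, gave 557 higher and 272 lower genes and a Cebpb difference of -0.35. It also gave medians of -0.24 for β-cell identity, 0.18 for adipocyte and erythrocyte markers and 0.095 for oxidative phosphorylation, which then lay within the random range, and of -0.24 for hypoxia and glycolysis and 0.19 for proteasome subunits, which then lay outside it. The cGAS-STING pathway was within the range without a floor (0.35) and with a floor of 5 FPKM (0.35), as were acute-phase genes with that floor (0.91, over 5 genes). Mitogenic signalling was lower than random lists with a pseudocount of 5 (-0.11), without a floor (-0.13), without shared members (-0.29), with equal sums (-0.29) and with the trend removed (-0.11). Markers of delta, PP and epsilon cells were higher with a pseudocount of 5 (0.57) and against unmatched random lists (0.58), and ductal markers without a floor (0.35). Beyond the construction of each setting, the cause was not tested. No paired analysis was possible because there is 1 library per genotype. Depth limits low genes such as Cgas, with at least 31 and 16 reads.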

Other observations

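Beyond the groups fixed in advance, genes of the early secretory pathway were lower in the library labelled KO; these 6 groups were chosen after seeing the data. Of 35 genes of ER translocation, signal peptidase and oligosaccharyltransferase, 7 were at least 2-fold lower and none higher, with a median of -0.49 below all random lists. Serp1, which stabilises nascent membrane proteins, was at 62.4 against 239 FPKM (3.83-fold, 3.66 to 4.01), and the signal recognition particle receptor Srpr and the translocon-associated Ssr3 had log2 ratios of -1.34 and -1.29. Of 33 genes of COPI and COPII vesicle coats and p24 cargo receptors, 8 were at least 2-fold lower and none higher, with a median of -0.50 below all random lists. Sec24d and Sec23b, of the coat that buds from the ER, were at -1.77 and -1.61, and Arcn1 and Copb1, of the coat that returns to it, at -1.43 and -1.39. After removal of the GC and length trend the medians were -0.46 and -0.44, still below the random range, and Ssr3 was at -0.91, no longer past 2-fold.

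Mitochondrial ribosomal proteins were higher, with a median of 0.45 above all random lists and 4 of 77 genes at least 2-fold higher. These included Mrpl52 (1.28), Mrpl54 (1.23) and Mrpl24 (1.23). After the trend was removed the median was 0.18 at percentile 99.5. Mrpl52 and Mrpl54, at 0.37 and 0.29, were then within 2-fold, and Mrpl24, at 1.07, was still past it. Cytosolic heat-shock proteins did not stand apart (median -0.17, percentile 10.8 over 14 genes), although the inducible Hspa1a, Hspa1b and Hspb1 were the 3 members at least 2-fold higher and Hspa4l was at -0.99; with the trend removed Hspb1 was at 1.23 and Hspa4l at -0.38. Neither did 284 Zfp zinc-finger genes (median -0.0024, percentile 3.27), 8 of them higher and 4 lower, with Zfp692 at 2.12 and Zfp652 at -1.35 (-0.88 with the trend removed). Cytosolic aminoacyl-tRNA synthetases had a median of -0.31 at percentile 3.28 over 17 genes, with Dars at -0.80 and Cars at 0.78.

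Of the tests below, those of the trend for acinar markers and for the 6 vascular, stromal, myeloid, interferon and inflammatory groups were set before their results were seen, and all others after. Cgas was 2.55-fold higher in the library labelled KO. Counting error of independent reads alone is argued against, since the lower limit of its interval was 1.35. Reads amplified by PCR are not independent molecules. With at least 31 and 16 reads, sampling error among fewer molecules therefore stays open. Cgas RNA from cells outside the β-cell lineage is a candidate explanation. Macrophage and dendritic-cell markers had a median ratio of 1.87, inside the Cgas interval, with Lyz2 at 91.3 and C1qa at 88.7 FPKM. None of these markers is in another list. The interval is wide, and endothelial, fibroblast and ribosomal protein genes were also higher (median log2 ratios 0.99, 0.80 and 0.86). The macrophage value therefore does not single out macrophages as the source. An exchange of labels stays open. With the driver of recombination not given, 0 genotype markers independent of Cgas could be named in the columns. That number rests on what the labels give, so it does not show that the columns lack such a marker. Ins1 was at 237131 FPKM in the library labelled KO and 113793 in WT, and Ins2, in the other direction, at 182558 and 250577. Neither was tested as a marker, and how reads were divided between them is uncertain. Reads outside a deleted exon and a partial deletion also stay open, since gene totals cannot show them.

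Acinar genes were 28 of 31 times at least 2-fold lower in the library labelled KO. The GC and length trend is argued against as the cause by its size. Medians of the 5 bins ran from -0.28 to 0.45 for GC content and from 0.47 to -0.26 for length. Against a group median of -3.34, removal of the trend was bound to leave a low median (-3.45), so that test adds no weight. More acinar tissue carried into the WT preparation, where islets were picked by hand, and a change in the acinar genes of the knockout animals cannot be told apart with 1 library per genotype. The share of markers past 2-fold, 90.3%, is the pattern itself and favours neither. In the WT library Ctrb1 reached 753 and Cela2a 292 FPKM.

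The remaining group differences were set against the GC and length trend, first with β-cell identity joined to the lower groups and with ribosomal and oxidative phosphorylation genes as one part; neither part came out whole (3 of 4 and 1 of 2 groups stayed apart), and both were then split. The trend is argued against as the whole cause for insulin granule (-0.37 after removal), ER stress (-0.52) and cholesterol genes (-0.38), whose medians stayed outside the random range. The same holds for the 6 higher vascular, stromal, myeloid, interferon, immediate-early and inflammatory groups, where 6 of 6 did. Ribosomal protein genes also stayed outside the range (0.45 after removal). Lengths were those of the longest annotated transcript for every gene, which need not be the expressed one. For ribosomal protein genes the trend therefore stays open, and the same limit weakens the answers for the other groups of this paragraph. The trend may account for the oxidative phosphorylation difference (0.095 after removal), and for β-cell identity the tests leave it open (-0.24 after removal). A lower share of β-cells would raise alpha-cell markers alike. Against that reference it is argued against as the whole cause for endothelial, fibroblast and macrophage markers. Their lowest lower quartile, 0.48, lay above the upper quartile of alpha-cell markers at 0.31. Delta-, PP- and epsilon-cell markers had a median of 0.58 and an upper quartile of 0.81, above 0.48. With those markers as reference the test would not decide, so on these values the answer depends on the reference. With the GC and length trend removed, the delta-, PP- and epsilon-cell median was 0.24. Endothelial, fibroblast and macrophage medians were then 1.01, 0.79 and 0.56. Quartiles were not computed with the trend removed, so the test was not repeated there. For the interferon, immediate-early and inflammatory groups a lower share of β-cells stays open, since their lowest lower quartile was 0.16. A different make-up of non-endocrine cells, handling of the islets before lysis and the genotype itself stay open for all 6.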
